A study of Homo sapiens with 34 samples.

How the data were processed

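The series holds 34 samples: 24 of RNA-seq, 8 of ChIP-seq and 2 inputs. Only the ChIP-seq peak lists of DLD1 cells were analysed; the RNA-seq samples and the signal tracks named in the labels were not used here. Per the labels' protocols, chromatin was sheared by sonication after formaldehyde fixation, and libraries were sequenced as single reads of 75 bp at 40 to 55M reads per sample. The groups are uninduced cells and cells given 1 µg/mL doxycycline for 24 h, with 2 samples for each antibody and condition. The labels name 1 peak list for both samples of a group. Whether reads were pooled before peaks were called is not given in the sources used here, so the replicates could not be compared.

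Per the submitters' processing notes, which give names without role or order, the tools were BWA 0.7.17-r1188, SAMtools 1.10, MACS2 2.1.1.20160309 and deepTools 3.5.0, beside RNA-seq tools. The notes name builds hg19 and hg38. The peak positions are on GRCh38, since chromosome 17 regions reach 83228308, past the end of that chromosome in GRCh37, and scaffold names are those of GRCh38. The authors' lists give, for each summit, a fold enrichment (a ratio over the caller's local background), a −log10 p and a −log10 q. The deposited −log10 q values begin at 1.30, so the lists hold what passed a q-value of that size. Filters and caller settings are not given in the sources used here. The deposited summit lists repeat the position and −log10 q of the peak lists at every summit and add nothing. Such values depend on depth and on the input used, so they served only to rank or describe regions within a list. No column of per-sample values went unmatched, since each list serves both samples of a group and holds no per-sample values.

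The lists held 177089 and 180063 summits for H3K27ac (uninduced and induced) and 109014 and 94939 for Pol II. Summits on chromosomes other than the 22 autosomes and X were left out, at most 0.603% of a list. Rows repeating a region for several summits were collapsed to 1 region with the highest −log10 q and fold of its summits. Coordinates are 1-based. Regions overlapped when they shared at least 1 bp; the full-list overlap counts equalled those of bedtools 2.31.1. Shares have Wilson 95% intervals, which cover counting error only.

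A region was called strong when among the 20000 highest of its list by −log10 q (ties by fold, then position). It was called strong in a condition alone when it also overlapped none of the 40000 highest of the other list. The 20000th region had a −log10 q of 88.5 and 77.1 for H3K27ac (uninduced and induced) and 20.3 and 13.5 for Pol II. Genes were the 19974 protein-coding genes of the RefSeq table of GRCh38.p14. That table gave no strand, so windows of 1 kb around both ends of a gene replaced the transcription start windows of the original plan, and distances to a gene are to its nearest end, or 0 within it. No genome sequence was used, so the planned search for the TCF motif near summits was not run.

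Pol II coverage is the percent of a gene's length that Pol II regions cover, for genes of 2 kb or longer covered in at least 1 list. Genes were counted when their difference lay over 25 percentage points from the median difference. The 10 gene lists were written before the data were examined: the guanylate cyclase C pathway (3 genes), Wnt and TCF targets (40), colonocyte differentiation (40), goblet and secretory genes (25), cell cycle and MYC-linked growth (30), interferon and inflammation (25), doxycycline and mitochondrial stress (19), housekeeping (20), immune, stromal and endothelial markers (20) and liver, muscle and neuron markers (20). These sizes are of genes matched to the gene table: the stress list was written with 20 symbols, of which 19 matched. A list's median difference was placed among 10000 random lists matched on coverage decile and gene length tertile. For H3K27ac, the number of list genes with an end within 50 kb of a region strong in a condition alone was placed among 10000 lists matched on quintiles of the number of strong regions nearby. The overlap of both marks was set beside 10000 draws of strong H3K27ac regions matched on gene-end window and −log10 q decile. Genes and regions are not replicates, so these percentiles describe the lists and are not p-values.

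The genes named were fixed by a rule before the data were examined. It took 8 genes in any case (GUCA2A, GUCA2B, GUCY2C, TCF7L2, AXIN2, LGR5, ASCL2 and MYC), up to 4 genes per list by nearness to a region strong in a condition alone or by Pol II coverage difference in the direction of the list's median, the 6 strongest such regions per mark and condition with the nearest gene within 100 kb, and the 6 genes of 5 kb or longer with the largest coverage difference each way, of which 1 is not reported here. A further measure was added after the data were seen. Each gene was placed, as a percentile among genes with a summit in either list, by the highest −log10 q of the summits within it or 1 kb of it.

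The procedures were tested on simulated lists made from the real ones. In a copy of the H3K27ac list, 200 strong regions were removed and 200 weak ones were given a high −log10 q; 100% were found each way with 0 false calls among 78005 regions, and likewise for Pol II among 57247 regions. Of 200 genes with coverage removed, 100% were found among 19974. Regions kept their places and the planted changes were large, so this checks the calculation and gives no error rate for the comparison of real lists. Alternatives changed the number of strong regions, the overlap rule, the ranking value, the thresholds, the gene-end window, the distance to genes and the part of the gene used. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.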

Results

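The chromatin data came from DLD1, a colorectal adenocarcinoma cell line, carrying a tetracycline-inducible transgene for a dominant negative form of TCF7L2. TCF7L2 is the transcription factor through which β-catenin drives Wnt target genes, and the dominant negative form blocks that step. Cells were left uninduced or given 1 µg/mL doxycycline for 24 h. Chromatin immunoprecipitation and sequencing was done with an antibody to H3K27ac, a histone mark of active promoters and enhancers, and with an antibody to RNA polymerase II (Pol II). Each antibody and condition had 2 samples, with 1 input sample per condition. The labels tie 1 peak list to both samples of a condition, so 4 lists were compared, no spread between replicates could be measured, and no difference below has a replicate check or a p-value. Another 24 samples, RNA-seq of 4 engineered colorectal cancer lines, were not analysed here.

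H3K27ac marked nearly the same places in both conditions. The uninduced list held 78005 regions covering 136.6 Mb, and the induced list 79987 regions covering 132.6 Mb. Of the uninduced regions 85.5% (Wilson 95% interval 85.2 to 85.7, counting error only) overlapped an induced region, and of the induced regions 87.7% (87.4 to 87.9) overlapped an uninduced one, with a Jaccard index of 0.799. The full Pol II lists differed more, mostly from the uninduced side. The uninduced list held 57247 regions over 70.9 Mb and the induced list 50665 regions over 56.7 Mb. Only 69.6% (69.2 to 70.0) of the uninduced Pol II regions met an induced region, against 89.2% (89.0 to 89.5) the other way, with a Jaccard index of 0.678. Among the 20000 strongest regions of each list the order turned, with 91.6% and 94.3% for Pol II against 90.5% and 91.3% for H3K27ac. Regions without a partner were mostly weak: their median −log10 q was 3.76 in the uninduced and 3.05 in the induced Pol II list. The peak lists give no read totals, so the depth behind each list is known only as the range in the labels, 40 to 55M reads per sample.

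The guanylin locus, the subject of the series' title, held an induced Pol II region that overlapped no uninduced one. GUCA2A encodes guanylin and GUCA2B uroguanylin, the peptide ligands of the intestinal receptor guanylate cyclase C, the product of GUCY2C. On chromosome 1 (GRCh38), GUCA2B lies at 42153410 to 42155820 and GUCA2A (gene 2980) at 42162690 to 42164745. This induced region lay at 42174389 to 42174987, between GUCA2A and FOXJ3. An uninduced Pol II region at 42173000 to 42173705 ended less than 1 kb before it. With regions within 1 kb taken as shared, the induced region was therefore not strong in the induced list alone. None of the 13 induced-alone windows found with 1 kb windows at summits overlapped it. The summit of the induced region lay 9.93 kb outside the upper end of GUCA2A, its fold enrichment was 8.00 and its −log10 q 22.3. Of the 5451 induced Pol II regions that overlapped no uninduced region, this one had the highest −log10 q. No H3K27ac region of either list overlapped it.

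Most of the other regions of the window had a partner in the other list. The H3K27ac region at the upper end of GUCA2A (42163595 to 42166716 in the uninduced list) had a fold of 15.04 and a −log10 q of 78.4. In the induced list it was split in 2, and the piece at 42163895 to 42166062 had a fold of 23.9 and a −log10 q of 128.4. The wide Pol II region that began at 42164528 and ended at 42171643 without induction had a fold of 13.9, and its induced counterpart at 42164593 to 42170902 a fold of 19.6. Inside FOXJ3 at the border of the window, the H3K27ac region at 42214176 to 42215487 had a fold of 7.60, against 13.0 for the induced region that begins at 42214167. The other paired H3K27ac regions went both ways. Named by their start in the uninduced list, 3 had a lower fold in the induced list (42133572 with 5.45 and 3.44, 42205939 with 3.47 and 2.57, 42206583 with 4.62 and 2.82) and 2 a higher one (42172966 with 4.03 and 4.25, 42177362 with 2.69 and 3.34). So did 2 smaller paired Pol II regions, at 42171845 (4.63 and 3.47) and 42173000 (3.74 and 4.36). At 42134333 to 42135080, on the far side of GUCA2B, an uninduced H3K27ac region with a fold of 5.81 had no induced partner, and induced H3K27ac regions at 42167633 to 42167917 and 42168043 to 42168684, with folds of 3.32 and 4.25, had no uninduced one. GUCA2B itself had no summit of either mark within 1 kb in either list. At GUCY2C the strongest H3K27ac summit had a −log10 q of 70.2 uninduced and 45.7 induced, and no Pol II summit was listed. These folds are the authors' own values for each list, and they are set side by side here without a test.

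**Figure D1:**
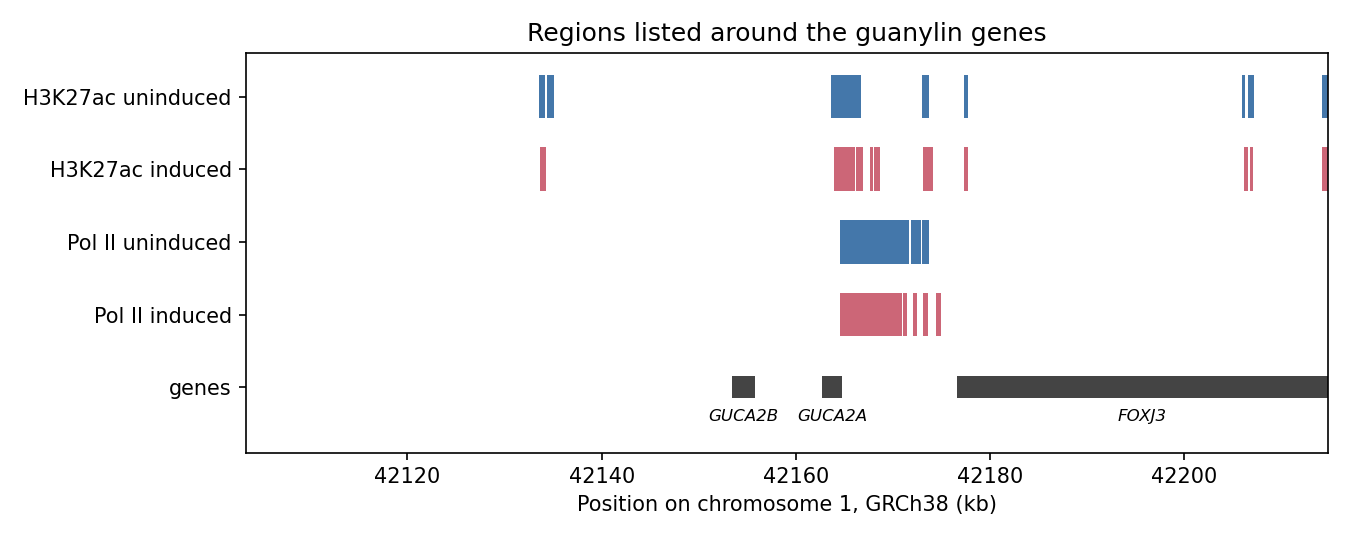
Map of the 111 kb around GUCA2B and GUCA2A on chromosome 1 (position in kb, GRCh38), with the H3K27ac and Pol II regions of the uninduced (blue) and induced (red) lists as boxes and genes in grey; features that reach past the window end at its border. The induced Pol II region at 42174389 to 42174987 has no uninduced box above it.

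Several Wnt target genes were covered by Pol II over less of their length in the induced list, though the list as a whole did not stand apart from other genes. Of the 36 genes of a list of Wnt and TCF targets that could be scored, 29 had a lower share of their body covered by Pol II regions in the induced list, 4 a higher share and 3 the same share. The lower ones made 80.6% of the list, against 77.9% of all scored genes. SP5, a transcription factor gene induced by Wnt, went from 78.2% covered to 45.6%. AXIN2, the usual readout of the pathway, went from 92.0% to 68.7%, and RNF43, a ubiquitin ligase gene of the pathway's negative feedback, from 49.8% to 35.6%. ADRA2C, which encodes an adrenergic receptor, went from 30.7% to 3.97%. The SP5 difference depended on the threshold: it was −17.4 points, in place of −32.6, both with regions of a −log10 q of at least 5 and with lists of equal length. The strongest Pol II summits did not follow coverage at all of these genes. Their places among genes of each list are percentiles, a measure chosen after seeing the data. AXIN2 (51.9 uninduced and 52.9 induced) and RNF43 (92.6 and 94.3) stood nearly level. SP5 stood higher in the induced list (57.1 and 64.2) and ADRA2C lower (69.6 and 21.8). The median difference of the list was −1.70 percentage points, at the 7.31 percentile of 10000 random gene lists of like coverage and length, inside the middle 95%.

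Other fixed targets differed less in coverage. MYC was covered over 68.6% and 63.8% of its body, a difference of −4.86 points, but of −13.1 with regions of a −log10 q of at least 5. ASCL2, a stem cell transcription factor gene, was covered over 100% in both lists. LGR5, the intestinal stem cell receptor gene, had 2.08% and 1.84%. For TCF7L2 itself the values were 2.21% and 2.74%, and its strongest H3K27ac summit had a −log10 q of 238.0 and 235.3. These values are of the endogenous gene and do not measure the transgene.

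**Figure D2:**
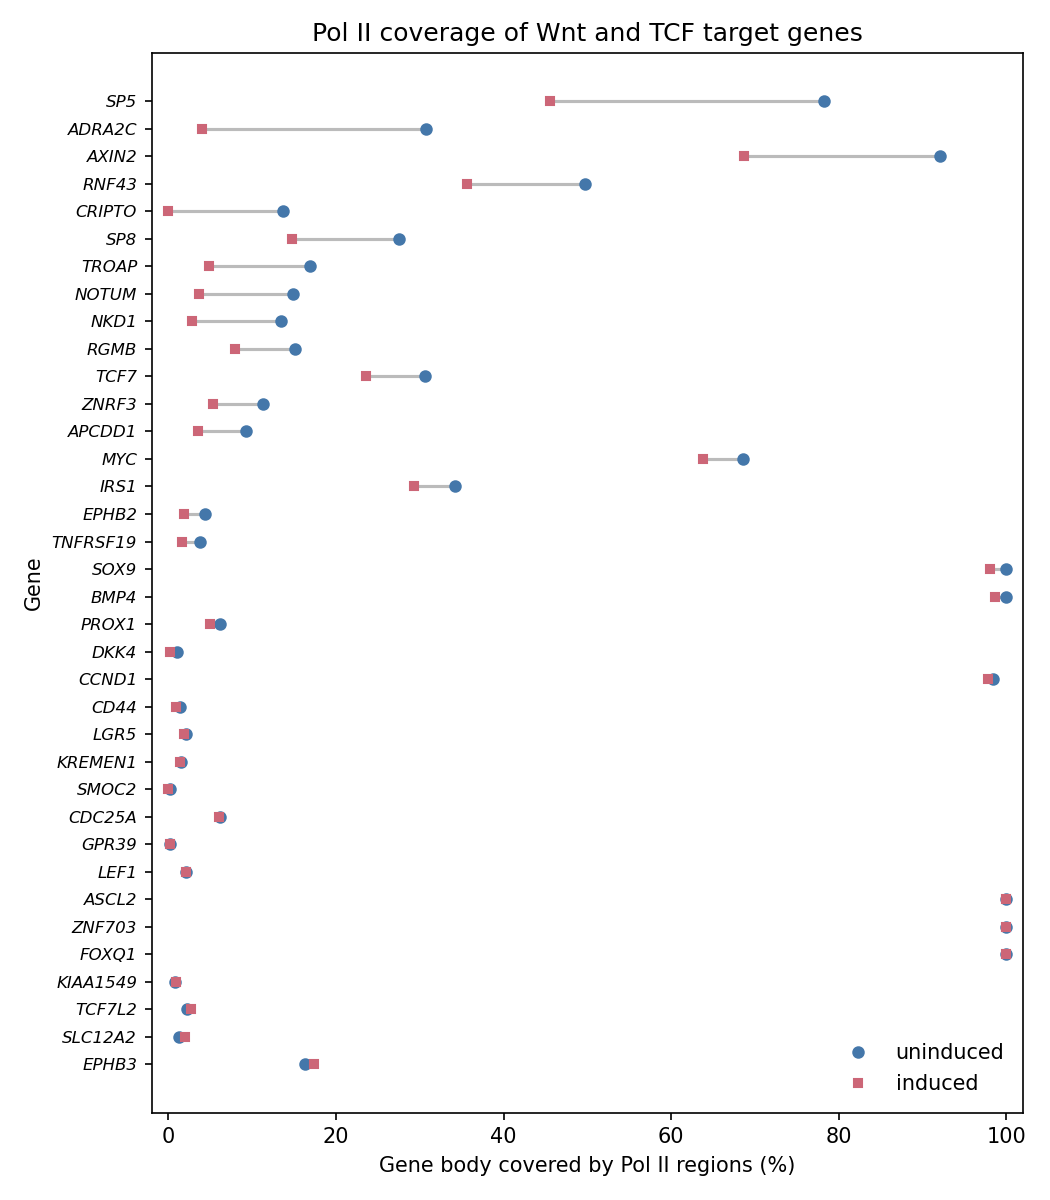
Percent of the gene body covered by Pol II regions (x axis) for each of the 36 scored Wnt and TCF target genes (y axis) in the uninduced (circles) and induced (squares) lists, ordered by the difference. SP5 (78.2% and 45.6%), ADRA2C and AXIN2 lie at the top.

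The scored genes of colonocyte differentiation were less reduced in Pol II coverage than random genes of like coverage and length. Their median difference was −0.131 points over 20 genes, at the 99.4 percentile of random lists, whose median was −1.38. The rest of the 40 genes had no Pol II coverage in either list, among them KRT20, FABP1 and CA4. The colonocyte list was 1 of 9 lists of more than 1 scored gene so placed. By the places of genes within each list, a measure chosen after seeing the data, the list lay inside the middle 95%, at the 75.9 percentile for Pol II and 89.4 for H3K27ac. TSPAN1, a tetraspanin gene, was covered over 51.5% uninduced and 64.5% induced, and CDX2, an intestinal transcription factor gene, over 68.6% and 76.5%. Both are named here after their values were seen. The place of the strongest Pol II summit went against coverage at CDX2 (88.5 and 79.0) and was nearly level at TSPAN1 (17.6 and 18.9). For H3K27ac the places were 98.8 and 94.9 at CDX2 and 54.8 and 85.2 at TSPAN1. Against the coverage of TSPAN1 and CDX2, EFNA1 had 51.8% and 37.7%, VIL1, the gene of the brush border protein villin, 7.18% and 1.53%, BEST4 45.1% and 40.4%, and KLF5 17.4% and 13.4%. In all, 11 of the 20 genes were lower and 9 higher. With regions of a −log10 q of at least 5 the differences were smaller for EFNA1 (−8.00 points) and VIL1 (−0.252).

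No other list with more than 1 scored gene stood outside the middle 95% of random lists. The goblet and secretory list had a median of −0.298 points (69.2 percentile), with AGR2 at 89.4% and 71.2% and KLK1 at 60.9% and 50.9%. Cell cycle and MYC-linked growth genes had a median of −0.670 (75.3 percentile), and CDK4 went from 100% to 71.7%. Interferon and inflammatory genes had −1.03 (28.4 percentile), with OAS1 at 27.7% and 12.9% and CXCL3 at 32.1% and 20.2%. Genes of doxycycline and mitochondrial stress had −1.47 (64.9 percentile), with GDF15 at 100% and 83.2%, TRIB3 at 37.8% and 21.3% and DDIT3 at 100% and 86.7%. Housekeeping genes had −2.47 (31.9 percentile), and ACTB was covered over 68.2% and 45.3%. Markers of immune, stromal and endothelial cells had −0.666 (19.0 percentile) and markers of liver, muscle and neurons −2.16 (11.7 percentile), with ACTA1 at 20.9% and 0%. With regions of a −log10 q of at least 5 the goblet and secretory list lay at the 9.97 percentile and the housekeeping list at the 96.8, still inside the middle 95%. At that limit the differences were smaller for TRIB3 (−3.69 points), ACTB (−5.94) and ACTA1 (−3.86). They were larger for KLK1 (−18.8), CDK4 (−48.0) and DDIT3 (−26.9). Only GUCA2A could be scored from the guanylate cyclase C list, with 10.6% and 7.44% covered. Its strongest Pol II summit within 1 kb went the other way, with a −log10 q of 11.4 uninduced and 48.5 induced. These were different summits of a wide region, at 42164728 uninduced and 42165400 induced. The strongest summit of that region lay outside the 1 kb, with a −log10 q of 64.2 uninduced and 92.5 induced. The rise near the gene may thus partly follow where summits were placed. By the summits within 1 kb the place of GUCA2A among genes was 7.55 uninduced and 20.3 induced, a measure chosen after seeing the data.

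Across all 14091 scored genes the induced list covered less. Coverage was lower in the induced list for 10975 genes and higher for 2898, with a median difference of −0.507 points. Relative to that median, 115 genes were lower by over 25 points and 4 were higher. Among genes of 5 kb or longer, the lowest were NSMF (94.1% and 36.1%), SUOX, the sulfite oxidase gene (63.0% and 10.9%), BTBD18 (90.0% and 40.9%), RRP36 (77.4% and 31.0%), TTPAL (65.8% and 21.7%) and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase gene (82.9% and 40.2%). Among the highest were FAM136A (29.5% and 49.98%), CDPF1 (31.8% and 48.2%), THYN1 (65.0% and 81.0%), WNT7B, which encodes a Wnt ligand (4.89% and 19.98%), and ATP5MK (7.15% and 21.7%). With regions of a −log10 q of at least 5 the differences were smaller for SUOX (−22.7 points in place of −52.2), FAM136A (12.1 in place of 20.4) and ATP5MK (2.01 in place of 14.6). The place of the strongest Pol II summit went against coverage at RRP36 (50.1 uninduced and 89.9 induced), CDPF1 (96.8 and 89.8) and THYN1 (80.1 and 68.9). It was nearly level at BTBD18 (8.85 and 10.0) and WNT7B (22.8 and 21.9). Coverage by regions says where signal passed the caller's threshold, so it also moves with the strength of the whole list.

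Strong H3K27ac regions seen in a single condition were more often those of the uninduced cells, by a margin that depended on the limits. Among the 20000 strongest regions of each list, 47 uninduced regions and 1 induced region overlapped none of the 40000 strongest of the other list. With the 10000 strongest against 20000 the counts were 79 and 2, with the 5000 strongest against 10000 they were 145 and 63, and with a −log10 q of 10 against 5 they were 2440 and 1210. Of the 47, 46 lay away from the ends of protein-coding genes, and 20 overlapped a gene. The strongest lay inside NTM, a neuronal adhesion gene, on chromosome 11 at 131518938 to 131522249, with a −log10 q of 210.0 and a fold of 25.4; the overlapping induced region had 10.4 and 4.22. The next was on chromosome 16 at 55042442 to 55048503, with no gene within 100 kb and a −log10 q of 168.5. Others lay inside FHOD3, a formin gene (chromosome 18, 36494176 to 36497614), 20.1 kb from HTATIP2 (chromosome 11, 20339826 to 20343587), inside CCDC148 (chromosome 2, 158189207 to 158193247) and inside RIMS2 (chromosome 8, 103539125 to 103542307). Of the 47, 46 still had a weaker induced region, whose median fold was 5.06 against 17.7 uninduced. The exception, 52.6 kb from RSPO2, which encodes a Wnt agonist, had no induced region at all (chromosome 8, 108136244 to 108137571, named after its values were seen). The induced region lay inside TMPRSS3 on chromosome 21 (42374140 to 42377587).

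Pol II showed the same lean under this rule, but not under every other. By this rule 103 uninduced and 14 induced regions were strong in a single condition, and 50 and 6 of these had no region of any strength in the other list. With 1 kb windows at summits in place of regions the lean turned round, to 2 uninduced and 13 induced, and with the 10000 strongest against 20000 there were 0 and 0. The strongest uninduced region was on chromosome 4 at 3835020 to 3838210, 66.5 kb from ADRA2C, with a fold of 7.15 and a −log10 q of 57.6. The H3K27ac regions there had folds of 17.2 uninduced and 6.66 induced. Next were regions 10.4 kb from ARHGAP20, inside SHC1, 47.7 kb from GATA5 and inside BABAM2, and a region on chromosome 2 at 204407544 to 204408065 with no gene within 100 kb. Of the 103 uninduced regions 99 lay on an H3K27ac region of the uninduced list and 96 on one of the induced list. This was no trait of theirs, since 93.3% of all strong uninduced Pol II regions lay on an uninduced H3K27ac region. The induced regions with the highest −log10 q were at RAB3D (24.9), beside FOXJ3 and GUCA2A (22.3), inside B3GNT3 (17.4), inside MMP28 (17.1), 67.5 kb from ALG1L2 (17.1) and at HBA2 (16.5), whose near-identical copy HBA1 makes that place uncertain.

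**Figure D3:**
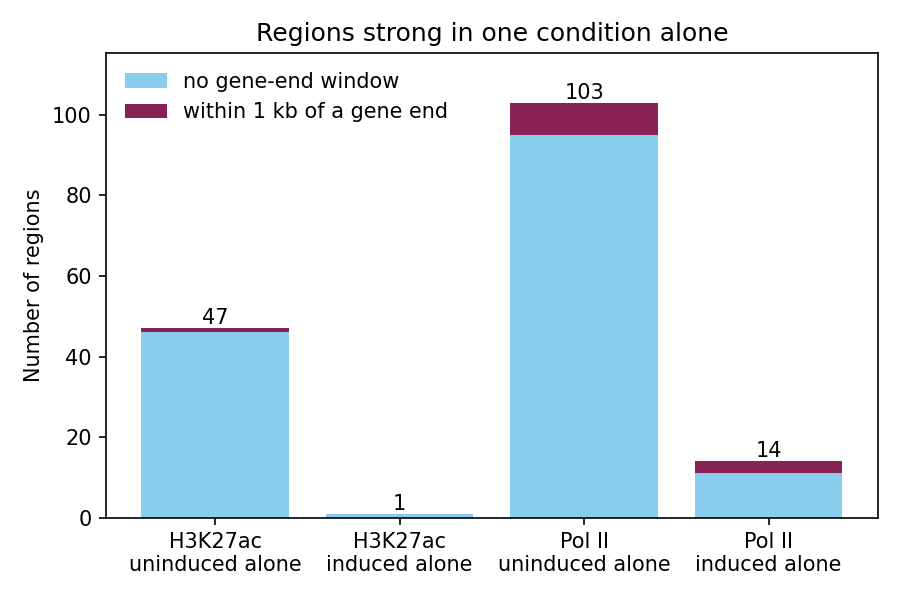
Number of regions (y axis) strong in the named condition alone for H3K27ac and Pol II, divided into those within 1 kb of either end of a protein-coding gene and the rest. The uninduced bars (47 and 103) exceed the induced bars (1 and 14), but with 1 kb windows at summits, not drawn here, the Pol II counts are 2 and 13.

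The uninduced-alone regions of both marks lay at gene ends less often than strong regions of like −log10 q. For H3K27ac, 2.13% (Wilson 95% interval 0.377 to 11.1) of the uninduced-alone regions were within 1 kb of either end of a protein-coding gene, against 46.9% (46.2 to 47.6) of the other strong regions. For Pol II the shares were 7.77% (3.99 to 14.6) against 58.0% (57.4 to 58.7) in the uninduced list, and 21.4% (7.57 to 47.6) against 58.4% (57.7 to 59.0) in the induced list. Matched on −log10 q, 10000 draws of as many strong regions held on average 13.5 gene-end regions for uninduced H3K27ac, where 1 was counted, and 24.4 for uninduced Pol II, where 8 were counted. For induced Pol II the 3 counted among 14 regions were close to the 3.42 of the draws. Other limits, chosen for this measure after seeing the data, differed. Ranked by fold, 3 of 40 were counted against 10.1 in draws, but 23 of 99 against 21.0 at a −log10 q of 10 against 5. The uninduced H3K27ac share was higher under other limits, chosen for this measure after seeing the data, but stayed below the draws: 22.1% with the 5000 strongest against 10000 (32 regions, against a mean of 93.0), 7.59% with the 10000 strongest against 20000 (6, against 39.6) and 8.04% when 50% of a region had to be covered (16, against 65.9). Induced-alone H3K27ac regions were short of gene ends as well: 37 of 1210 at a −log10 q of 10 against 5 (75.5 in draws), 7 of 44 with 1 kb windows at summits (17.9) and 5 of 35 when 50% had to be covered (11.2). With the 5000 strongest against 10000 they were not, at 40 of 63 (41.2).

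Few such regions were called for either mark, and few coincided. Of the 47 uninduced-alone H3K27ac regions, 1 overlapped an uninduced-alone Pol II region. Matched draws held 0.248 on average, and 2180 of 10000 had as many. Counting Pol II regions of any strength, 16 of the 47 met one of the uninduced list and 0 met one of the induced list. Of all strong uninduced H3K27ac regions, 90.4% met an uninduced Pol II region. None of the genes of the 10 fixed lists lay with an end within 50 kb of an uninduced-alone H3K27ac region, Wnt targets included. Only 45 genes did in all, 0.225% of protein-coding genes. Random lists like the Wnt list held 0 to 1, so a count of 0 says nothing about Wnt targets. Near the induced-alone region lay 4 genes, among them TFF1, a trefoil factor gene of the goblet list (99.8 percentile of random lists for that list). That value rests on 1 gene and 1 region: with the 10000 strongest against 20000 the list had 0 genes (49.6 percentile), and with regions within 1 kb taken as shared there were 0 induced-alone regions. Near the Pol II regions, ASNS, the asparagine synthetase gene, lay within 50 kb of an uninduced-alone region, and GUCA2A and GUCA2B within 50 kb of the induced-alone region described above.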

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

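No paired analysis was possible because 1 list serves both replicates of a condition; for that reason no replicate could be left out either. The TCF motif alternatives were not run, and coverage without the first 1 kb of a gene was replaced, after seeing the data, by coverage without 1 kb at either end. The cause of the differences below was not tested, except that stricter or looser limits change how many regions can be called. For H3K27ac regions strong in a condition alone (47 uninduced, 1 induced), the counts were 79 and 2 with the top 10000 against 20000, 145 and 63 with the top 5000 against 10000, 1 and 0 with no overlap of any region, 2440 and 1210 at a −log10 q of 10 against 5, 199 and 35 when 50% of the region had to be covered, 81 and 10 ranked by fold, 327 and 44 with 1 kb windows at summits, and 43 and 0 with regions within 1 kb shared. The uninduced count was higher in each. For Pol II (103 and 14) the same settings gave 0 and 0, 1 and 0, 50 and 6, 2167 and 99, 455 and 23, 202 and 40, and, reversed, 2 and 13 with summit windows. With regions within 1 kb shared they were 92 and 10, and the region beside GUCA2A was not among the 10. Overlap of H3K27ac regions (uninduced, then induced) was 86.9% and 91.0% at a −log10 q of at least 5, 88.4% and 92.7% at 10, 81.3% and 84.6% with 50% covered and 90.5% and 91.3% for the top 20000; for Pol II it was 75.1% and 94.6%, 79.7% and 97.2%, 60.3% and 84.7%, and 91.6% and 94.3%. Gene-end shares of other strong regions were 46.0% and 48.5% (H3K27ac uninduced), 56.3% and 60.9% (Pol II uninduced) and 56.1% and 61.7% (Pol II induced) with windows of 500 bp and 2 kb; those of regions strong in a condition alone were 2.13% with both (H3K27ac uninduced), 5.83% and 12.6% (Pol II uninduced) and 21.4% and 42.9% (Pol II induced). For H3K27ac uninduced, the gene-end share was no longer below draws only with no overlap of any region, which left 1 region and a share of 0%; this alternative was chosen after seeing the data. With the top 10000 against 20000, 0 gene lists stood outside random lists for induced H3K27ac (1 before) and 0 regions were shared by both marks (1 before). Genes over 25 points higher in Pol II coverage were 8 and lower 189 at a −log10 q of at least 5, and 10 were higher with lists of equal length. At a −log10 q of at least 5, beside SP5, SUOX, FAM136A and ATP5MK, named genes with smaller differences were EFNA1 (−8.00 points), VIL1 (−0.252), LGR5 (−0.0516), TRIB3 (−3.69), ACTB (−5.94) and ACTA1 (−3.86). Beside MYC, those with larger ones were KLK1 (−18.8), CDK4 (−48.0) and DDIT3 (−26.9). With lists of equal length EFNA1 had −8.00, VIL1 −2.36, CDPF1 31.2 and THYN1 24.97. The Wnt list's percentile stayed inside the middle 95% (10.1 and 4.33) and the colonocyte list's outside it (98.6 and 98.1) under those 2 settings. Overlap was lowest among the weakest regions, at 32.5% of the uninduced Pol II regions ranked past 40000.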

Other observations

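The places of genes within each list, a measure chosen after seeing the data, add detail on Wnt targets and on stress genes. By their strongest H3K27ac summit, 26 of 39 Wnt targets had a lower place in the induced list and 13 a higher one, and 24 of 36 were lower by Pol II. LGR5 was at the 98.6 percentile uninduced and 81.2 induced for H3K27ac, and at 66.1 and 50.2 for Pol II. APCDD1, a Wnt inhibitor gene, was at 68.3 and 35.8 for H3K27ac, NKD1 at 91.8 and 70.7, and EPHB2, an ephrin receptor gene, at 57.5 and 33.3 for Pol II. By the other mark NKD1 (97.6 and 97.3 for Pol II) and EPHB2 (87.1 and 86.9 for H3K27ac) stood nearly level. APCDD1 was at 45.6 and 37.3 for Pol II. SP5 was higher in the induced list for H3K27ac, at 81.1 uninduced and 97.3 induced. The median shift of the list was at the 10.5 percentile of random lists for H3K27ac and 5.99 for Pol II. With summits up to 5 kb outside the gene these were 5.68 and 1.06, and ranked by fold they were 29.7 and 20.6, so the place of the list depends on the measure. Higher places in the induced H3K27ac list included GUCA2A (21.2 and 38.9), TSPAN1 (54.8 and 85.2) and the secretory genes SPDEF (46.2 and 72.1) and AGR2 (56.6 and 84.9), although the goblet and secretory list as a whole lay at the 54.5 percentile, with 6 genes lower and 11 higher. The genes in this paragraph other than the fixed ones were named after their values were seen, and the places describe each list and measure no change in amount.

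All but 3 of the tests below were chosen before their result was seen; those on gene ends, on background and on stress genes were chosen after it. The first pattern is the lean of strong H3K27ac regions to the uninduced list. Splitting of broad regions would bring the counts together with 1 kb windows at summits. The counts went from 47 and 1 to 327 and 44, a ratio of 7.43, so they came closer in proportion but the lean remained. Only 3 of the 327 windows overlapped the 47 regions, so that test speaks of the lean and not of those regions. A part played by splitting stays open. Loss at enhancers of Wnt targets may contribute and stays open: the percentile of that list was 45.4, but random lists held 0 to 1 genes, so a count of 0 could not tell. Under the main rule regions are chosen by rank, which an equal weakening of the induced library would leave as it is. A weakening that left ranks and region borders as they are would not by itself give this lean. Whether borders were kept was not tested, and the median region width was 1159 bp uninduced and 1040 bp induced. The counts of 2440 and 1210 use limits of −log10 q and not ranks, so the argument does not cover them. Weaker enrichment that differs between regions may contribute and stays open. Of the 47 regions 1 was at a gene end, against a lowest count of 4 in 10000 draws. That count decides nothing, since induced-alone regions were short of gene ends as well (37 of 1210, against a mean of 75.5, at a −log10 q of 10 against 5). A biological loss away from genes was not tested.

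The second pattern is the shorter Pol II list after induction. Lower depth of the induced libraries may account for it and stays open. The local background implied by fold and p was 0.814 times that of the uninduced list. Such values depend on the input as well, with 1 input sample per condition. So the ratio cannot tell the depth of the Pol II libraries from that of the input. The H3K27ac ratio was 0.872, although that list was not shorter. A biological loss of Pol II was not tested apart from depth, since read totals were not used here.

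The third pattern is the induced Pol II region between GUCA2A and FOXJ3. Its place among the 14 induced-alone regions could be chance, and the draws made do not decide this: 6 of 10000 draws of 14 strong induced regions had a region in the window fixed around the guanylin genes, but only 2 of the 20000 strong regions lie there, so the limit of 500 draws set beforehand could not have been reached. The region was also known when that test was written. A response of the guanylin locus to dominant negative TCF7L2 was not tested.

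A last hypothesis concerned stress genes, whose Pol II places were lower in the induced list for 16 of 19 genes, among them ASNS (76.8 and 49.9), SESN2 (94.7 and 67.5) and CHAC1 (93.4 and 69.3). Random lists of like level and length could give such a median shift: the list lay at the 4.66 percentile, inside the middle 95%. Ranked by fold it lay at the 0.53 percentile, outside it, so the answer depends on the ranking value.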
